A study of Homo sapiens with 12 samples.

How the data were processed

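The data are 12 Affymetrix arrays of RNA from HK-2 cells, 3 from each of 4 groups: Ota or control, for 24 h or 72 h. The groups follow the labels. The deposited values are log2 GCRMA expression values per probe set, which the authors made; GCRMA is named in the submitters' processing notes with no version, and the set of arrays used for the normalization and any later filter are not stated. The values were used on the log2 scale as deposited. The table held 54675 probe sets, of which 62 were Affymetrix controls, and 0 columns belonged to samples outside the series. The platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777; of those with 1 symbol 41043 were matched to a current gene record by their gene identifier, and 0 symbols had to be updated. No genome build is named, so no positions are given.

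A probe set entered the gene comparisons if it had 1 symbol and a value over 4 on at least 3 of the 12 arrays, and each gene was represented by the probe set with the highest mean over the 12 arrays. This left 10729 genes, 5153 of them with more than 1 probe set over the filter. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (residual degrees of freedom 8, prior degrees of freedom 3.56). The contrasts were Ota against control at 24 h, the same at 72 h, the difference between these effects, and control cells at 72 h against 24 h. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Single values per array, such as the control probe sets, were compared by exact permutation over the 10 splits of 3 against 3 arrays. Means over 24 poly-A spike-in, 18 hybridization control and 3 18S ribosomal RNA probe sets were taken per array. The number of arrays limits the precision, and an array has no read depth.

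The 22 gene lists, 5 lists of cell type markers, comparisons and tests, and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and limma's fry beside it. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Named genes were the 8 largest rises and 8 largest falls in each Ota comparison among genes past the threshold whose 3 Ota arrays all lay on the same side of all 3 controls, and the 5 largest in each direction past the threshold in the other comparisons. From each list up to 3 members with the largest change past the threshold were named, with the 1 largest in the other direction, or up to 2 with the smallest p where no member passed. Some list members are not reported by name.

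Whether equal replicate numbers pair the arrays was checked at 24 h by correlating deviations from the group means. Pairs of equal number had r = 0.12, 0.23 and 0.27, each the best match of its array, so a fit with the replicate number as a block was run as an alternative. The other alternatives fixed beforehand were quantile normalization, centring each array on its median, no filter or a value over 6, the mean over a gene's probe sets, all probe sets fitted, leaving out probe sets marked as cross-hybridizing, a variance trend with robust moderation, array weights, an absolute log2 fold change of at least 1, an adjusted p under 0.01, the 6 arrays of a comparison alone, and leaving out each array in turn. Scaling each array to its poly-A spike-ins was chosen after seeing the data, as were centring for the lists and for the correlation between times, and leaving out arrays for that correlation. The fit was tested on simulated data in which 200 of 10729 genes were changed. At log2 changes of 0.5, 1, 2 and 4 it recovered 14%, 48%, 96% and 100% of 50 genes each. Of its calls 4.44% were unchanged genes, a raised list was called, and 0 of 50 unchanged lists were. The simulated genes varied independently, with an equal spread in all groups and without array-wide shifts. The simulation therefore does not show how the list test performs where genes of a list vary together. Nor does it show the share of false calls where groups differ in spread or most genes change.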

Results

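Gene expression was measured in HK-2 cells, an immortalized line of epithelial cells from the human kidney's proximal tubule, to find expression signatures of toxicity. The cells had received a high dose of a compound that the labels call Ota, or its vehicle, for 24 h or 72 h. The labels give neither the full name nor the amount. The 4 groups held 3 Affymetrix arrays each, 12 arrays in all. The labels call the arrays of a group biological replicates and do not otherwise say whether the cultures were separate, so p-values measure the spread between these samples. The deposited GCRMA values are on a log2 scale and cover 54675 probe sets, of which 10729 stood for 1 tested gene each. The number of arrays limits the precision, and the median standard error of a log2 fold change between 2 groups was 0.21. It rests on a spread shared by all groups.

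The arrays separated by treatment and, within treated and control cells, by time. The first principal component held 56.7% of the variance and placed all Ota arrays apart from all control arrays. The second held 26.7% and separated the Ota arrays of 24 h from those of 72 h. Correlations between arrays of 1 group ranged from 0.979 to 0.997. Several array-wide measures also differed between Ota and control arrays. The median of the tested genes was 7.40 ± 0.16 (SD, n = 3) on the Ota arrays and 7.97 ± 0.05 (SD, n = 3) on the control arrays at 24 h. At 72 h it was 7.68 ± 0.05 and 7.96 ± 0.02 (SD, n = 3 each). Poly-A spike-ins, bacterial transcripts that standard protocols add before labelling, were brighter on the Ota arrays by 1.85 at 24 h and 0.89 at 72 h on the log2 scale. Probe sets for 18S ribosomal RNA were brighter by 1.58 and 1.34. In each of these 4 differences all 3 Ota arrays lay above all 3 controls (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow). The 3' minus 5' difference of the ACTB control probe sets, a measure of RNA integrity, was 1.97 ± 0.33 with Ota and 1.39 ± 0.15 in controls at 72 h (SD, n = 3 each; exact permutation p = 0.1). At 24 h it differed by 0.046 (exact permutation p = 0.9), and that of GAPDH by 0.031 at 24 h and 0.033 at 72 h (exact permutation p = 0.3 and 0.7).

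**Figure D1:**
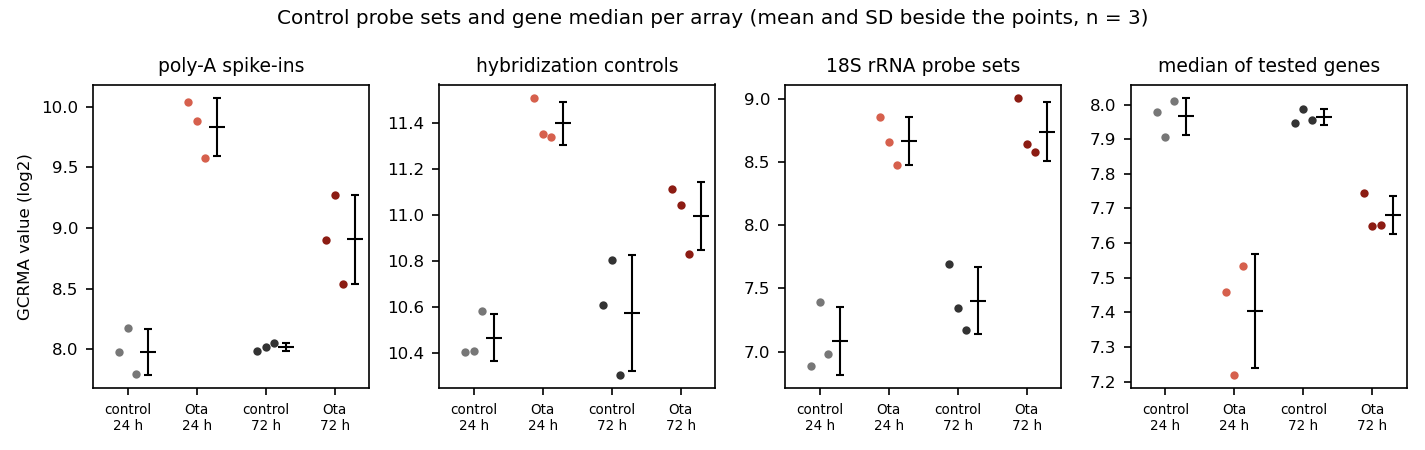
Log2 GCRMA values per array (vertical axes) of the poly-A spike-ins, the hybridization controls, the 18S ribosomal RNA probe sets and the median of the tested genes, by group (horizontal axes); points are arrays, and bars are the mean and SD of 3 arrays. The poly-A spike-ins averaged 9.83 on the Ota arrays and 7.98 on the control arrays at 24 h.

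The array-wide differences bear on every direction given below. The median log2 fold change of all tested genes was -0.24 at 24 h and -0.11 at 72 h, and 0.17 for the difference between times. Quantile normalization moved the 24 h median by 0.21, centring each array on its median moved it by 0.56, and scaling to the poly-A spike-ins moved it by -1.85. At 72 h centring moved it by 0.28 and the spike-in scaling by -0.89; for the difference between times the shifts were -0.16, -0.28 and 0.96 in the same order. Medians of gene lists are therefore given relative to that of all tested genes, unless called own medians or drawn in a plot, while sizes of single genes are log2 fold changes ± SE from the limma fit of all 12 arrays. A gene "rose" or "fell" where limma's Benjamini-Hochberg adjusted p was under 0.05.

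At 24 h, FGF18, a fibroblast growth factor, showed the largest rise with Ota, from 2.89 ± 0.10 to 11.17 ± 0.22 (SD, n = 3; log2 fold change 8.29 ± 0.55, limma adjusted p = 2.1e-07). FRZB, which encodes a secreted antagonist of Wnt proteins (from 2.61 to 9.11), MSH4, a gene of meiotic recombination (6.38 ± 0.18), AVIL, which encodes the actin-binding protein advillin (6.36 ± 0.23), the histone gene H2BC4 (5.68 ± 0.27) and AOC3, which encodes an amine oxidase (5.60 ± 0.37), also rose. The largest fall was that of TMEM37, from 9.76 ± 0.16 to 2.70 ± 0.76 (SD, n = 3; -7.06 ± 0.47, limma adjusted p = 2.3e-07). NBPF20 (-6.62 ± 0.38), TMEM139 (-6.45 ± 0.42), PET117 (-6.24 ± 0.35), METTL23 (-6.20 ± 0.14), the CTP synthase gene CTPS1 (-6.14 ± 0.44), CARD10 (-6.04 ± 0.54) and NABP1 (-5.88 ± 0.48) followed. For each of these genes all 3 Ota arrays lay on the same side of all 3 control arrays. The rule for naming the largest changes required this. PABPC1L (5.81 ± 0.32) and DCTN5 (5.48 ± 0.41) were also among the 8 largest rises, but another probe set of each gene went the other way, at -3.91 for PABPC1L and -2.86 for DCTN5. Of TMEM37's 4 probe sets, 3 shared its direction. The control means of FGF18, FRZB, MSH4, AVIL, H2BC4 and AOC3 were under 4, the level set for the filter, as were the Ota means of TMEM37 and the other 7 falls named above, so each of these fold changes sets a clear signal against a near-background one and their order is uncertain.

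**Figure D2:**
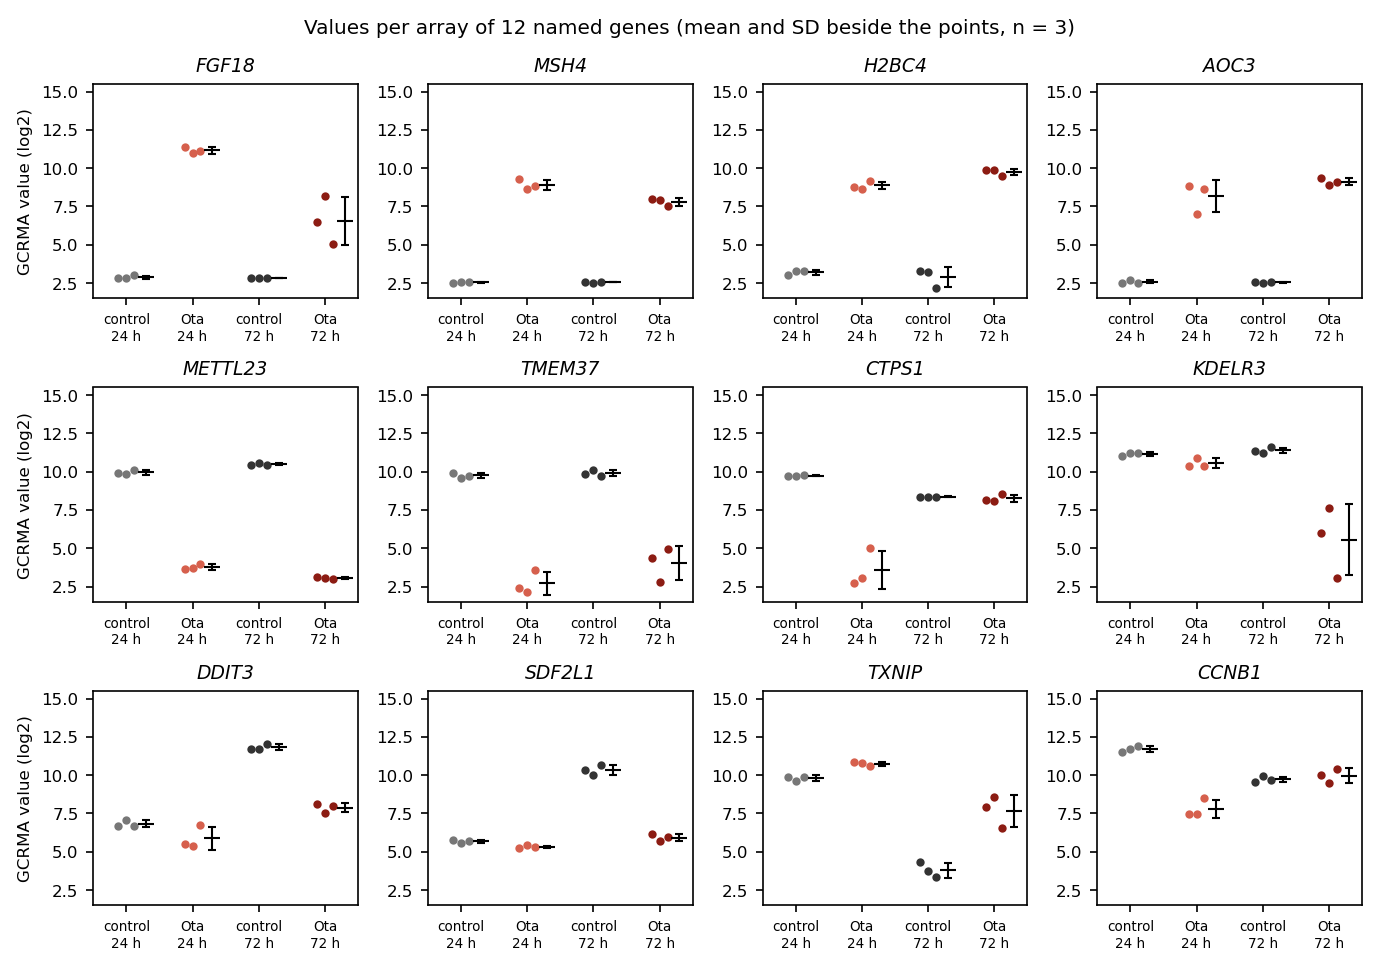
Log2 GCRMA values (vertical axes) of 12 named genes on each array, by group (horizontal axes); points are arrays, and bars are the mean and SD of 3 arrays. FGF18 rises from 2.89 in control cells to 11.17 in Ota cells at 24 h, and DDIT3 is at 11.84 in control cells and 7.87 in Ota cells at 72 h.

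Histone genes were the gene list that stood out upwards at 24 h. Of 12 measured members 9 rose and 2 fell, with a median 3.14 above that of all genes (limma's camera, adjusted p = 3.0e-05; adjusted p = 0.38 with an estimated correlation), and with the spike-in scaling 7 rose and 3 fell. H2AC6 (5.33 ± 0.32) and H2AC8 (3.51 ± 0.38) rose, as did H2BC4 above, while the chosen probe set of the variant H2AX fell (-2.06 ± 0.17) and its other probe set went the other way. DNA replication genes went down together. Of 25 measured, 18 fell and 0 rose, with a median of -0.95 relative to all genes (camera, adjusted p = 0.0104; adjusted p = 0.82 with an estimated correlation). Among them were the clamp loader genes RFC4 (-4.02 ± 0.23) and RFC3 (-3.70 ± 0.46) and the origin licensing gene CDC6 (-2.40 ± 0.41). Of 27 mitosis genes 15 fell and 1 rose, including the cyclin gene CCNB1 (-3.90 ± 0.30) and the proliferation marker MKI67 (-3.47 ± 0.24), but the list did not pass the test (camera, adjusted p = 0.0823). With centring 6 mitosis genes rose and 9 fell, and with the spike-in scaling 0 rose and 27 fell. The list's exception TTK (0.80 ± 0.19) lay below 0, at -1.05, with the spike-in scaling. The remaining 19 lists did not pass either. For each of the 30 list results past the threshold in the 4 comparisons, the adjusted p with an estimated correlation was the highest over that result's alternatives, and 6 of the 30 passed with it.

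Genes of several stress and signalling lists changed in both directions at 24 h, and with the spike-in scaling at most 1 member of any list but the histones rose. Of all 10729 tested genes 2236 rose and 4343 fell at 24 h. These lists did not pass camera, so counts in both directions do not by themselves set a list apart, here or in the next paragraph. With centring more members rose than fell among ATF4 targets (9 and 6), NF-kB genes (5 and 1), apoptosis regulators (6 and 4) and heat shock genes (4 and 2), against the counts below. Among 18 p53 target genes 11 fell and 2 rose; CCNG1 (-2.93 ± 0.14), the death receptor gene FAS (-2.84 ± 0.46) and the DNA damage binding gene DDB2 (-2.74 ± 0.29) fell, and RRM2B was higher by 0.90 ± 0.20, or -0.95 with the spike-in scaling. Among 21 ATF4 targets of the integrated stress response 6 rose and 9 fell, with the transcription factor gene ATF3 rising (3.61 ± 0.25) and DDIT4, an inhibitor of mTOR signalling, falling (-4.39 ± 0.16). Of 18 endoplasmic reticulum chaperone genes 7 rose and 2 fell; the falls were XBP1 (-2.02 ± 0.32) and HSPA5 (-1.03 ± 0.16), each with 1 of 2 probe sets in that direction, and the mean over its probe sets put HSPA5 at 1.09. Of 18 NRF2 targets 5 rose and 3 fell; the aldo-keto reductase genes AKR1C1 (-2.75 ± 0.25) and AKR1C3 (-2.29 ± 0.26) fell. Of 16 immediate early and MAPK feedback genes 9 fell, such as SPRED1 (-3.38 ± 0.35), and EPHA2 rose (1.97 ± 0.38). Of 14 NF-kB and cytokine genes 3 rose, led by TNFAIP3 (2.76 ± 0.39), and 4 fell, led by CCL2 (-2.39 ± 0.47). Of 17 interferon-stimulated genes 9 fell and 3 rose, with IFI35 (-3.76 ± 0.24) and PSMB9 (-3.00 ± 0.43) lowest. Of 14 apoptosis regulators 6 fell and 1 rose; MCL1 (-2.14 ± 0.20) and CASP9 (-1.74 ± 0.26) fell. Of 5 AHR targets 3 rose and 2 fell; AHRR, the receptor's repressor, rose (3.27 ± 0.26) and CYP1B1 fell (-2.79 ± 0.37). Of 11 heat shock genes 0 rose and 3 fell, among them CHORDC1 (-3.24 ± 0.41) and DNAJB1 (-3.08 ± 0.39). Of 8 metallothionein genes 2 rose and 2 fell, the falls including MT1E (-1.01 ± 0.12).

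Kidney and metabolic lists at 24 h were likewise mixed, apart from proximal tubule genes, and centring turned the balance of kidney injury markers (7 risen, 5 fallen), epithelial junction genes (6 and 5) and ribosome biogenesis genes (6 and 2). It gave 12 risen and 1 fallen hypoxia genes, and 17 and 0 for oxidative phosphorylation. Of 25 proximal tubule genes 5 were measured and 4 of them fell, among them the tubule transcription factor gene PAX8 (-2.53 ± 0.40) and the bicarbonate transporter gene SLC4A4 (-2.22 ± 0.21); the list did not pass (camera, adjusted p = 0.27). Of 18 kidney injury markers 4 rose and 7 fell. VCAM1 (-3.87 ± 0.29) and KRT19 (-2.42 ± 0.35) fell, and CD44 was higher by 1.78 ± 0.24 as deposited but at -0.07 with the spike-in scaling. Of 15 epithelial junction genes 3 rose and 6 fell, including the tight junction genes OCLN (-2.63 ± 0.54) and CLDN1 (-2.40 ± 0.32). Of 15 extracellular matrix and TGF-beta genes 5 rose and 1 fell, with the smooth muscle gene TAGLN rising (3.06 ± 0.44). Of 16 cholesterol genes 9 fell and 1 rose, among the falls NSDHL (-2.73 ± 0.25) and SQLE (-1.94 ± 0.21). Of 20 hypoxia and glycolysis genes 4 rose, with ALDOC (2.81 ± 0.31) and ADM (2.29 ± 0.20) highest, and 4 fell. Of 22 oxidative phosphorylation genes 7 rose and 2 fell; NDUFB8 was higher by 0.54 ± 0.14, or -1.31 with the spike-in scaling. Of 17 ribosome biogenesis genes 1 rose and 7 fell, among them NOP16 (-1.32 ± 0.27). Markers of other cell types gave few values: 0 of 8 endothelial and 0 of 8 leukocyte markers were measured. LUM, a fibroblast marker, was higher by 0.69 ± 0.22 (-1.16 with the spike-in scaling) but did not pass without Ota replicate 1 (0.54) or control replicate 2 (0.46) of 24 h. AQP3, a collecting duct marker, was higher by 1.09 ± 0.26 (-0.76), and the podocyte markers PTPRO (0.18 ± 0.23) and PODXL (-0.33 ± 0.15) did not pass the test. Adjusted over the list alone, the counts at 24 h were 3 risen and 11 fallen for p53 targets, 3 and 2 for NF-kB genes, 1 and 10 for immediate early genes, 4 and 1 for matrix genes, 5 and 1 for oxidative phosphorylation, 1 and 6 for ribosome biogenesis and 0 and 2 for heat shock genes; the other lists had the counts given.

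In all, 6579 genes changed at 24 h by limma, 2236 upwards and 4343 downwards, and 4040 of them by a log2 fold change of at least 1. Rises made up 34.0% of the calls as deposited, 45.2% after quantile normalization, 61.9% after centring and 1.49% of 10187 calls with the spike-in scaling. The groups did not overlap for 65.7% of genes, where chance gives 10%. Without replicate 3 of the Ota group at 24 h 6 lists passed, and without replicate 1 of its controls 4 did, against 2 with all arrays; 7 passed with no filter on the values and 5 with the mean over probe sets.

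At 72 h, histone genes lay higher and ATF4 targets lower in Ota than in control cells, the lists that passed with an estimated correlation (camera, adjusted p = 0.0437 and 0.0261). H2BC4 rose from 2.89 ± 0.63 to 9.75 ± 0.20 (SD, n = 3; log2 fold change 6.86 ± 0.27, limma adjusted p = 8.0e-09), and H2BC9 (5.27 ± 0.20) and the linker histone gene H1-2 (5.26 ± 0.18) rose with it. AOC3 (6.58 ± 0.37), the urokinase receptor gene PLAUR (5.91 ± 0.23), SPMIP1 (5.90 ± 0.21), GAL, which encodes the peptide galanin (5.46 ± 0.30), ZNF513 (5.31 ± 0.20) and MSH4 (5.27 ± 0.18) were the other largest rises. METTL23 fell the most, from 10.49 ± 0.06 to 3.04 ± 0.06 (SD, n = 3; -7.45 ± 0.14, limma adjusted p = 3.9e-11). RUFY1 (-6.16 ± 0.33), GPR160 (-6.03 ± 0.33), the peptide hormone gene SPX (-6.03 ± 0.24), TMEM37 (-5.86 ± 0.47), KDELR3, which encodes a receptor that returns proteins to the endoplasmic reticulum (-5.83 ± 0.81), the nuclear envelope gene SYNE2 (-5.76 ± 0.39) and WDR13 (-5.70 ± 0.39) followed. In each of these genes all 3 Ota arrays lay on the same side of all 3 control arrays, as the rule for naming the largest changes required. The control means of H2BC4, H1-2, AOC3, SPMIP1, GAL, ZNF513 and MSH4 and the Ota means of METTL23, RUFY1, GPR160, SYNE2 and WDR13 were under 4, so these fold changes and their order rest on near-background values.

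All 12 measured histone genes rose at 72 h, and 10 rose with the spike-in scaling; the median lay 4.04 above that of all genes (camera, adjusted p = 2.5e-09; adjusted p = 0.0437 with an estimated correlation). Of 21 ATF4 targets 18 fell and 0 rose, with a median of -1.84 relative to all genes (camera, adjusted p = 4.0e-06; adjusted p = 0.0261 with an estimated correlation). They included the folate enzyme gene ALDH1L2 (-4.80 ± 0.38) and DDIT3, which encodes the stress factor CHOP (-3.97 ± 0.31). Of 18 endoplasmic reticulum chaperone genes 12 fell and 0 rose, at a relative median of -1.28 (adjusted p = 0.00107; adjusted p = 0.46 with an estimated correlation), led by SDF2L1 (-4.42 ± 0.18) and HYOU1 (-3.23 ± 0.24). Interferon-stimulated genes were lower, with 12 of 17 fallen and 2 risen at a relative median of -1.29 (adjusted p = 0.0155; adjusted p = 0.46 with an estimated correlation); PSMB9 (-3.71 ± 0.43) and IFI44L (-3.23 ± 0.23) fell and OAS3 rose (2.05 ± 0.22). Of 8 metallothionein genes, which encode metal-binding proteins, 7 fell and 0 rose at a relative median of -1.76 (adjusted p = 0.00432; adjusted p = 0.46 with an estimated correlation), such as MT1F (-2.72 ± 0.18) and MT1X (-2.06 ± 0.21).

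Lists of division, cholesterol synthesis, ribosome biogenesis and heat shock lay higher in Ota cells at 72 h, and their unadjusted medians depended on the scaling. Of 27 mitosis genes 17 rose and 3 fell, at 1.04 above all genes (camera, adjusted p = 5.0e-04; adjusted p = 0.46 with an estimated correlation), with TTK (1.90 ± 0.19) and BIRC5 (1.70 ± 0.15) among them; with the spike-in scaling 3 rose and 6 fell. Of 25 replication genes 13 rose and 3 fell, at 0.85 above all genes (adjusted p = 0.00107; adjusted p = 0.46 with an estimated correlation), including the cyclin genes CCNE2 (2.51 ± 0.17) and CCNE1 (2.31 ± 0.24), while RFC4 fell (-4.57 ± 0.23); with the spike-in scaling 4 rose and 6 fell (own median -0.16). Of 16 cholesterol biosynthesis genes 8 rose and 0 fell, at 0.74 above all genes (adjusted p = 0.0142; adjusted p = 0.46 with an estimated correlation), for example NSDHL (1.23 ± 0.25) and the sterol sensor gene INSIG1 (0.97 ± 0.18), but with the spike-in scaling 0 rose and 4 fell (own median -0.26). Of 17 ribosome biogenesis genes 10 rose and 0 fell, at 0.66 above all genes (adjusted p = 0.0107; adjusted p = 0.46 with an estimated correlation), with BRIX1 highest (1.74 ± 0.25), but with the spike-in scaling 1 rose and 3 fell (own median -0.34). Of 11 heat shock genes 6 rose and 1 fell, at 0.57 above all genes (adjusted p = 0.0461; adjusted p = 0.46 with an estimated correlation), including BAG3 (2.23 ± 0.17) and HSPH1 (2.12 ± 0.29), but with the spike-in scaling 3 rose and 3 fell (own median -0.43). The heat shock call by camera also ended with quantile normalization (adjusted p = 0.0595), with centring (0.0515) and with the filter at 6 (0.0580). It ended too without Ota replicate 2 or 3 of 24 h, Ota replicate 1 or 3 of 72 h or control replicate 3 of 72 h (up to 0.0674). The adjusted p ranged from 7.4e-04 by fry, which does not compare with other genes, to 0.46 by camera with an estimated correlation.

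**Figure D3:**
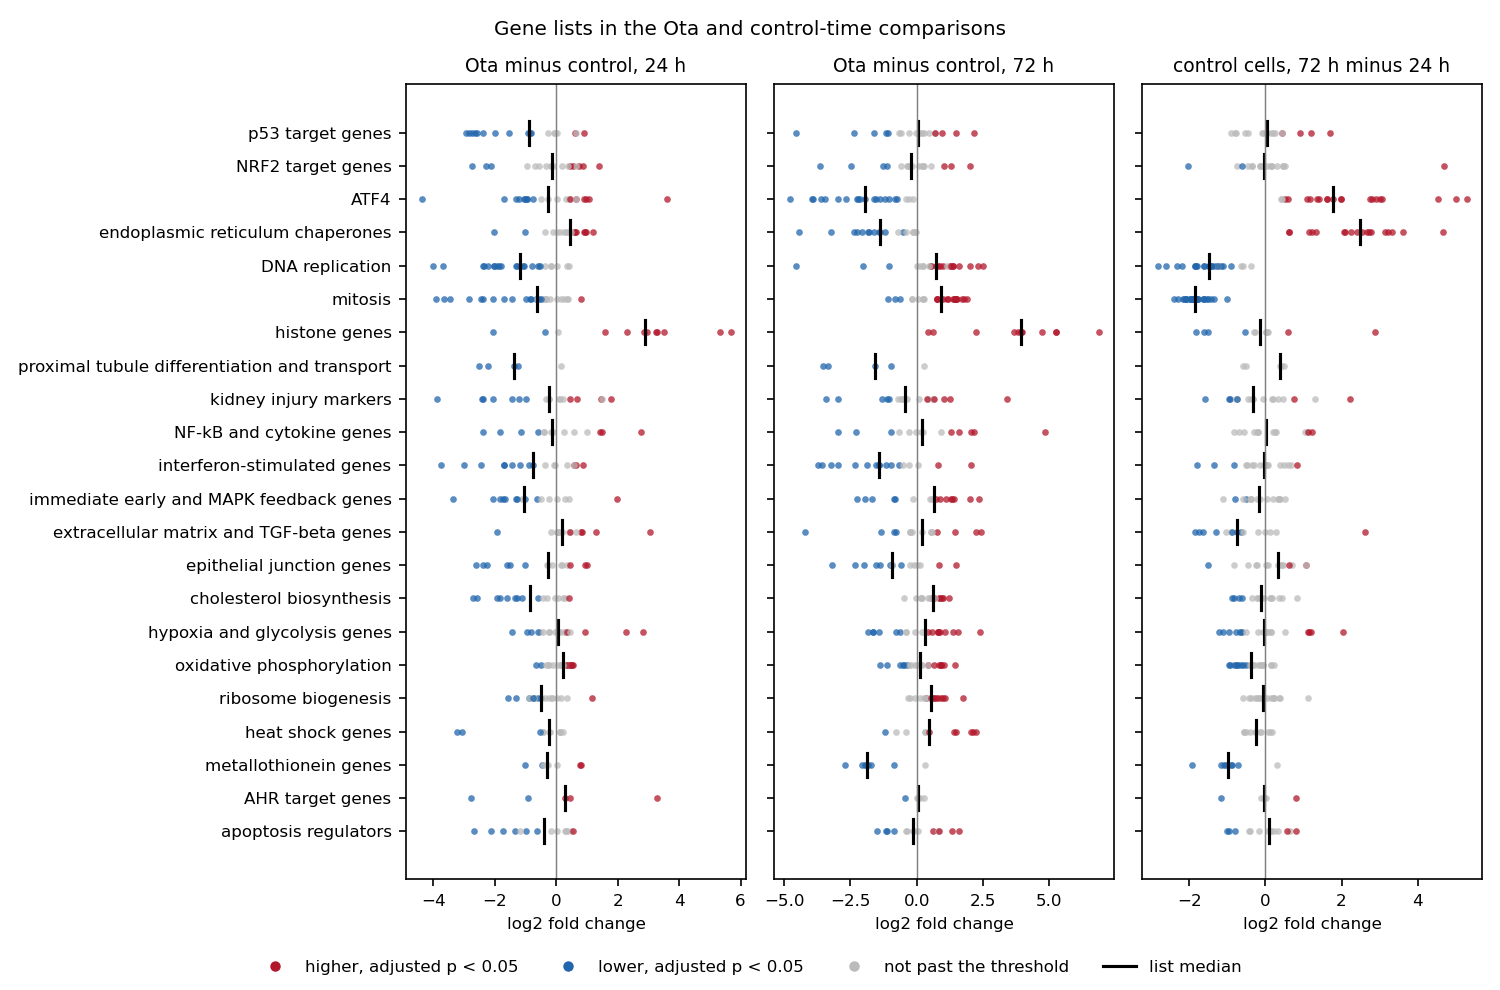
Log2 fold change (horizontal axes) of each measured member of the 22 gene lists (vertical axis) for Ota against control cells at 24 h and 72 h and for control cells between the times; points are genes coloured by their limma result, and bars are list medians. The histone median is 2.90 at 24 h and 3.92 at 72 h, and with the spike-in scaling the 72 h medians of the replication, cholesterol, ribosome biogenesis and heat shock lists, drawn above 0, lie below 0.

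The other lists did not pass at 72 h, and with the spike-in scaling at most 2 members of any of them rose. Of all 10729 tested genes 2665 rose and 3780 fell at 72 h, so the counts below do not by themselves set a list apart. Of 18 p53 targets 4 rose and 5 fell, with the cell cycle inhibitor gene CDKN1A (2.17 ± 0.19) rising and TP53I3 (-4.56 ± 0.26) falling. Of 18 NRF2 targets 3 rose and 4 fell, with the glutathione synthesis gene GCLM (2.02 ± 0.30) rising and the cystine transporter gene SLC7A11 (-3.66 ± 0.22) and NQO1 (-2.48 ± 0.34) falling. Of 5 proximal tubule genes 4 fell, including SLC4A4 (-3.52 ± 0.21) and the amino acid transporter gene SLC3A1 (-3.34 ± 0.21), at a relative median of -1.47 (camera, adjusted p = 0.0732). By camera that list passed without Ota replicate 3 of 72 h (adjusted p = 0.0237) and with centring (0.0459). Its adjusted p ranged from 7.2e-06 by fry, which does not compare with other genes, to 0.94 by camera with no filter. Of 18 kidney injury markers 5 rose and 5 fell, with CD44 rising (3.39 ± 0.24) and VCAM1 (-3.42 ± 0.29) and CD24 (-2.97 ± 0.14) falling. Of 14 NF-kB and cytokine genes 5 rose and 3 fell. IL6 was at 7.47 ± 2.39 with Ota and 2.62 ± 0.24 in controls (SD, n = 3, limma adjusted p = 4.0e-04). The limma fit shares a single spread per gene among all groups, so that p understates the wide spread of IL6 on the Ota arrays. Of 16 immediate early genes 8 rose and 5 fell, with EGR1 falling (-2.24 ± 0.23). Of 15 matrix genes 4 rose and 4 fell, with LOX falling (-4.23 ± 0.25) and TGFBI rising (2.41 ± 0.23). Of 15 epithelial junction genes 2 rose and 8 fell, the falls including E-cadherin, CDH1 (-3.18 ± 0.28). Of 20 hypoxia and glycolysis genes 10 rose and 6 fell, of 22 oxidative phosphorylation genes 8 rose and 6 fell, of 14 apoptosis regulators 4 rose and 4 fell, and of 5 AHR targets 0 rose and 1 fell. The markers LUM (1.55 ± 0.22), AQP3 (2.02 ± 0.26) and PTPRO (0.65 ± 0.23, or -0.24 with the spike-in scaling) were higher with Ota, but PTPRO did not pass without Ota replicate 2 or 3 or control replicate 1 or 2 of 72 h (0.44 to 0.65). Adjusted over the list alone, the counts at 72 h were 13 fallen for chaperones, 14 risen for replication, 18 risen for mitosis, 7 risen for cholesterol, 3 risen for matrix genes and 0 fallen for AHR targets; the others had the counts given.

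In all, 6445 genes changed at 72 h by limma, 2665 upwards and 3780 downwards, and 3994 of them by a log2 fold change of at least 1. Rises made up 41.3% of the calls as deposited, 56.1% after centring and 7.63% of 7273 calls with the spike-in scaling. The groups did not overlap for 73.7% of genes, where chance gives 10%.

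Control cells themselves changed between 24 h and 72 h, in the lists of stress response and division. All 18 chaperone genes rose, at 2.48 above all genes (camera, adjusted p = 1.7e-19; adjusted p = 0.0305 with an estimated correlation), among them SDF2L1 (4.67 ± 0.18), CRELD2 (3.61 ± 0.26) and HYOU1 (3.34 ± 0.24). Of 21 ATF4 targets 19 rose and 0 fell, at 1.77 above all genes (adjusted p = 7.1e-18; adjusted p = 6.0e-04 with an estimated correlation), such as ATF3 (5.29 ± 0.25) and DDIT3, from 6.82 ± 0.23 to 11.84 ± 0.18 (SD, n = 3; 5.02 ± 0.31, limma adjusted p = 1.9e-06). All 27 mitosis genes fell, at a relative median of -1.86 (adjusted p = 1.7e-22; adjusted p = 0.0694 with an estimated correlation), including MKI67 (-2.41 ± 0.24). Of 25 replication genes 21 fell and 0 rose, at a relative median of -1.47 (adjusted p = 9.6e-18; adjusted p = 0.0273 with an estimated correlation), among them UHRF1 (-2.84 ± 0.17) and the thymidine kinase gene TK1 (-2.61 ± 0.28). TXNIP, a glucose-induced gene that encodes a thioredoxin-binding protein, fell the most, by 6.02 ± 0.41 to 3.79 ± 0.49 (SD, n = 3).

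**Figure D4:**
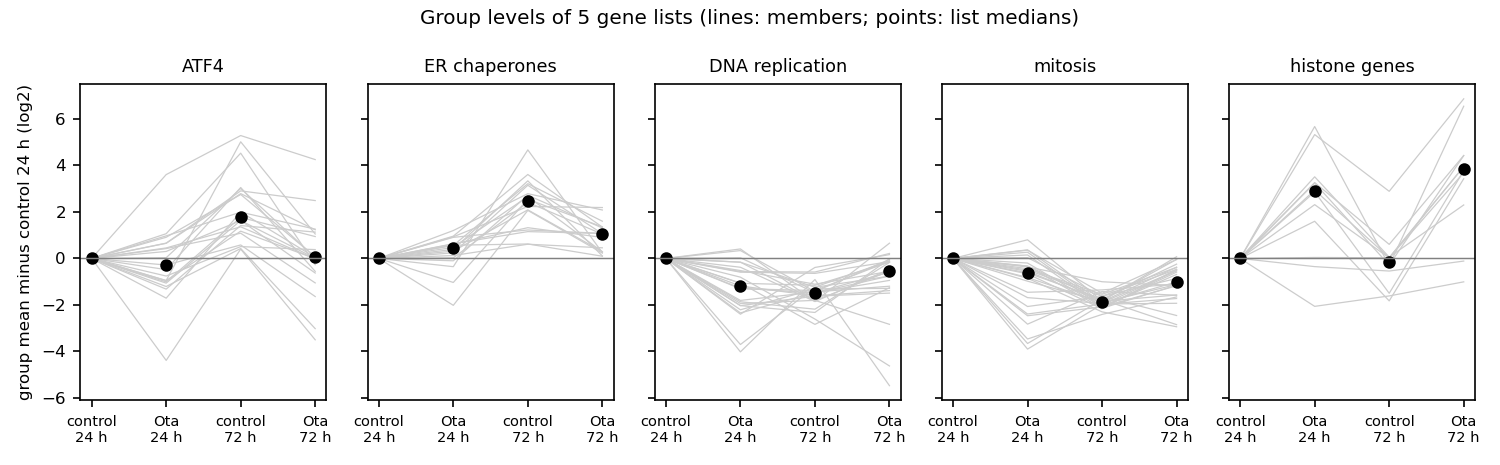
Group mean of each member gene minus its mean in control cells at 24 h (vertical axes, log2) in the 4 groups (horizontal axes), for 5 gene lists; grey lines are genes and black points list medians. In control cells at 72 h the points lie at 1.77 for ATF4 targets and 2.48 for chaperones, and in Ota cells at 72 h they lie at 0.04 and 1.06.

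Among single genes in control cells, the other largest rises were INHBE (5.88 ± 0.38), an activin subunit gene, and SLC7A11 (4.71 ± 0.22), and the other largest falls GAL (-4.15 ± 0.30), the sodium channel gene SCN3A (-3.74 ± 0.41), GINS4 (-3.47 ± 0.40) and the condensin gene NCAPH (-3.26 ± 0.28). The 72 h means of TXNIP, GAL, SCN3A and GINS4 were under 4, so the sizes and order of these falls are uncertain. Of 8 metallothionein genes 7 fell, at a relative median of -0.97 (camera, adjusted p = 1.2e-04; adjusted p = 0.18 with an estimated correlation). Of 22 oxidative phosphorylation genes 10 fell and 0 rose, at -0.39 (adjusted p = 6.3e-04; adjusted p = 0.0912 with an estimated correlation), for example ATP5MC3 (-0.83 ± 0.14). Of 15 matrix genes 7 fell and 1 rose, at -0.74 (adjusted p = 0.0209; adjusted p = 0.57 with an estimated correlation), with TGFBI falling (-1.86 ± 0.23) and LOX rising (2.61 ± 0.25). The matrix call ended with the mean over probe sets (adjusted p = 0.0678), without control replicate 1 of 24 h (0.0548) and without control replicate 2 of 72 h (0.0567), over a range of 0.00375 to 0.57. The fibroblast markers DCN (-1.79 ± 0.41) and LUM (-1.77 ± 0.22) fell with the matrix genes, and the podocyte marker PTPRO fell (-1.35 ± 0.23). Of the histone genes 2 rose and 4 fell, of the cholesterol genes 0 rose and 4 fell, and of the heat shock and ribosome biogenesis genes 0 rose and 0 fell. Adjusted over the list alone, 20 ATF4 targets rose, and 24 replication, 13 oxidative phosphorylation and 8 matrix genes fell, with the same counts for chaperones, mitosis and metallothionein genes. In all, 2739 genes changed by limma, 1313 upwards and 1426 downwards; the 2 groups did not overlap for 53.5% of genes, where chance gives 10%. That count was 1210 at a log2 fold change of at least 1, 1280 with the spike-in scaling and 4309 in a fit of the 6 control arrays alone.

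The Ota effects at the 2 times shared part of their direction. Across the tested genes, which are not independent replicates, the log2 fold changes at 24 h and 72 h correlated with Pearson's r = 0.52 and Spearman's rho = 0.49. Of the calls 1175 genes rose at both times, against 555 for independent lists of that size, and 2320 fell at both, against 1530. Another 391 fell at 24 h and rose at 72 h, against 1079, and 261 rose and then fell, against 788.

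Where the Ota effect differed between the times, division and heat shock genes were among the lists with higher effects at 72 h, and ATF4 targets and chaperones among those with lower ones. The effect on POLQ, which encodes DNA polymerase theta, was 6.70 ± 0.34 higher at 72 h than at 24 h (limma adjusted p = 7.5e-07), since POLQ stood at 6.80 in control and 3.02 in Ota cells at 24 h, and at 3.82 and 6.74 at 72 h. CTPS1 (6.04 ± 0.63), the nuclear pore gene NUP85 (5.87 ± 0.70), CARD10 (5.50 ± 0.76) and LSM6 (5.34 ± 0.57) stood between 3.60 and 4.82 in Ota cells at 24 h and between 8.25 and 9.07 at 72 h. The largest differences downwards were ALDH1L2 (-5.86 ± 0.53), KDELR3 (-5.24 ± 1.15), GPR160 (-5.10 ± 0.46), the glycine metabolism gene GCAT (-5.06 ± 0.32) and TMEM256 (-5.02 ± 0.70). POLQ, CTPS1, CARD10 and LSM6 had Ota means under 4 at 24 h, ALDH1L2, GPR160 and GCAT had them at 72 h, and control means under 4 were those of POLQ at 72 h and ALDH1L2 at 24 h, so the sizes and order of these differences are uncertain. Of 27 mitosis genes 25 had a higher effect at 72 h and 0 a lower one (relative median 1.44; camera, adjusted p = 2.2e-07; adjusted p = 0.36 with an estimated correlation). The list's own median between 24 h and 72 h was -0.30 in Ota cells and -1.86 in control cells. Of 25 replication genes 22 had a higher effect and 1 a lower one (1.84; adjusted p = 5.9e-07; adjusted p = 0.25 with an estimated correlation). Immediate early (12 of 16 higher, 1.06; adjusted p = 0.0181), heat shock (7 of 11, 1.77; 0.0227), cholesterol (10 of 16, 1.14; 0.00443), histone (9 of 12, 1.10; 0.00430) and ribosome biogenesis genes (10 of 17, 0.63; 0.0119) also had higher effects. In the same order the adjusted p with an estimated correlation was 0.46, 0.45, 0.46, 0.35 and 0.47. Lower effects at 72 h were found for ATF4 targets (14 of 21, -2.10; adjusted p = 1.0e-06), chaperones (15 of 18, -1.52; 2.6e-07), metallothionein genes (7 of 8, -1.80; 6.6e-05) and interferon-stimulated genes (7 of 17, -0.76; 0.0472), the last with an own median of -0.60 that became 0.37 with the spike-in scaling. With an estimated correlation ATF4 targets passed (adjusted p = 0.0223), and the adjusted p was 0.25 for chaperones, 0.25 for metallothionein genes and 0.36 for interferon-stimulated genes.

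Adjusted over the list alone, 15 ATF4 targets had lower effects, and 23 replication and 11 cholesterol genes had higher ones. For histones 10 were higher and 2 lower, for heat shock genes 8 and 1, and the other lists named here had the counts given. The interferon call by camera ended with quantile normalization, centring, no filter and the mean over probe sets. It ended too without Ota replicate 1 or 2 of either time or control replicate 3 of 72 h (adjusted p up to 0.0814). The adjusted p ranged from 0.00631 by fry, which does not compare with other genes, to 0.36 by camera with an estimated correlation. The immediate early call ended with the spike-in scaling (adjusted p = 0.0570; range 6.1e-04 to 0.46) and the ribosome biogenesis call with the mean over probe sets (adjusted p = 0.0605; range 1.0e-05 to 0.47). In all, the Ota effect differed between times in 5313 genes by limma, 3178 with a higher and 2135 with a lower effect at 72 h. Higher effects made up 59.8% of these as deposited, 46.9% after centring and 91.9% with the spike-in scaling. Of the 5313, 1217 fell with Ota at 24 h and did not pass at 72 h, 897 fell at 72 h and did not pass at 24 h, and 391 fell at 24 h and rose at 72 h.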

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

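Of the tests in this part, those of labelling, spike amount, messenger RNA share and batches for the spike-ins, of S phase and paralogs for the histones, and of the control cells' own change for the stress genes were chosen after the result was seen; the scaling of the arrays to the spike-ins was likewise added after seeing the data.

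A signal in probe sets outside the gene comparisons separated Ota from control arrays. Poly-A spike-ins were higher on the Ota arrays by 1.85 at 24 h and 0.89 at 72 h, hybridization controls by 0.93 and 0.42, and 18S ribosomal RNA probe sets by 1.58 and 1.34 (log2, 3 against 3 arrays). A lower share of messenger RNA in the total RNA of Ota cells may account for the poly-A spike-ins and 18S, since the latter rose by 1.58 at 24 h. Less labelled target or dimmer hybridization stays open, as does another amount of spike mix for the poly-A spike-ins alone, since these exceeded hybridization controls of like brightness by 0.57 at 24 h (SD between arrays 0.21) but only 0.383 at 72 h (SD 0.28). Separate labelling or hybridization batches cannot be told apart from treatment either, because all 6 Ota arrays lay above the controls of their time.

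Histone genes were higher with Ota, by an own list median of 2.90 at 24 h and 3.92 at 72 h. More cells in S phase is argued against at 24 h, where the replication list had an own median of -1.18 with 18 of 25 members fallen. At 72 h that median was 0.73 against control cells of 72 h, so a part in the rise stays open, but against those of 24 h it was -0.56 while the histone median was 3.86, which argues against S phase as the whole cause. Against control cells of 24 h the replication and histone medians were -0.27 and 4.15 with centring. There 10 of 25 replication members lay above those cells and 15 below. With the spike-in scaling the medians were -1.48 and 2.94. The histone median of control cells over time (-0.13) decides nothing, since 4 of the 12 members were under 4 there at 24 h. A single transcript read by the probe sets of all risen members is argued against by rises in 4 histone families at each time. Paralogs read by each other's probe sets within a family, such as the H2BC genes, were not excluded, so the risen members may hold fewer separate signals. Scaling is argued against by 10 members that rose at 72 h with the spike-in scaling. Whether more histone transcripts carried a poly-A tail stays open.

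ATF4 targets and endoplasmic reticulum chaperones were lower with Ota at 72 h. Scaling is argued against, since 28 of the 30 members that fell did so with centred arrays. The change of the control cells may account for part of the difference, but how much depends on the scaling: in Ota cells at 72 h the own list median against control cells at 24 h was 0.041 for ATF4 targets and 1.06 for chaperones, or -0.88 and 0.13 with the spike-in scaling. A candidate explanation for the control cells is glucose shortage in their medium by 72 h, and ARRDC4, a glucose-induced gene like TXNIP, fell there (log2 fold change -1.21 ± 0.32, limma adjusted p = 0.0159). Medium glucose was not measured, and an effect of Ota on these pathways stays open beside it.

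The Ota effect differed between times in 5313 genes by limma's test of the difference. Of 100 draws of the array labels, the real one included, 2 gave as many genes, the other with 5900. The draw with 5900 exchanged the times within one arm, and the highest of the rest gave 3605. Exchanging times also alters each arm's own change over time. The draws therefore do not test the difference alone, and they cannot exclude chance. For Ota at 24 h (6579 genes), Ota at 72 h (6445) and control cells over time (2739), the 10 splits are too few for a share under 0.05; 1 split, the real one, gave as many genes, and the highest other gave 0, 0 and 1. At 24 h, where each array correlated best with that of equal replicate number, 3 other splits part all pairs of equal number and gave at most 0 genes.

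The test of the difference also picked out gene lists, given as the own median difference of the Ota effect, 72 h minus 24 h, not relative to all genes. With an estimated correlation 1 of these 11 lists passed, ATF4 targets (adjusted p = 0.0223), and the others had an adjusted p of 0.25 to 0.47. The median was -1.93 for ATF4 targets, -1.35 for chaperones, 2.01 for DNA replication, 1.60 for mitosis, 1.27 for histones, 1.23 for immediate early genes, 1.31 for cholesterol, 0.80 for ribosome biogenesis, 1.94 for heat shock and -1.63 for metallothionein genes. For interferon-stimulated genes it was -0.60, or 0.37 with the spike-in scaling. The genes with the largest differences were POLQ (6.70), CTPS1 (6.04), NUP85 (5.87), CARD10 (5.50) and LSM6 (5.34) upwards, and ALDH1L2 (-5.86), KDELR3 (-5.24), GPR160 (-5.10), GCAT (-5.06) and TMEM256 (-5.02) downwards.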

How the results depend on the processing

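The spike-in scaling, and centring for lists, were chosen after seeing the data; the cause was not tested for any change below unless the setting itself tests fewer genes or arrays or is stricter. Of 251 named-gene results past the threshold 229 passed in every fit without one array. Ranges over the fits without one array were 5870 to 6648 genes for Ota at 24 h, 5753 to 7110 at 72 h, 4633 to 5888 for the difference and 1913 to 3583 for control cells over time, 0.47 to 0.57 for the correlation between times, and 2 to 6, 9 to 10, 10 to 11 and 6 to 7 lists. At an absolute log2 fold change of at least 1 the counts were 4040 at 24 h, 3994 at 72 h and 1210 in control cells, which had 1547 at an adjusted p under 0.01, 4309 in a fit of 6 arrays and 5434 with array weights; the weight estimation stopped before converging and gave one array 66.2 and another 0.101. A fit of the 6 arrays of the comparison alone gave 5720 genes for Ota at 24 h and 7115 at 72 h. The median SD within a group was 0.31 for Ota and 0.18 for control cells at 24 h, and 0.21 and 0.13 at 72 h. The main fit shares a single spread per gene among these groups, so it understates the spread of the Ota arrays of 24 h. With the spike-in scaling 10187 genes changed at 24 h and 1280 in control cells. Lists past the threshold at 24 h numbered 7 with no filter, 5 with the mean over probe sets, 0 with an estimated correlation and 15 by fry; with an estimated correlation 2 passed at 72 h, 1 for the difference and 3 in control cells, and fry called 16 at 72 h. Fry's direction was down and camera's up for ATF4 targets (relative median -0.045) and kidney injury markers (0.011) at 24 h and p53 targets (0.17) at 72 h. With the spike-in scaling these 24 h values changed sign: RRM2B -0.95, GCLM -0.44, DNAJC3 -0.65, TTK -1.05, CD44 -0.071, IFIT2 -0.996, TGFBI -0.55, KRT7 -0.86, SREBF2 -1.43, NDUFB8 -1.31, NDUFV2 -1.34, BRIX1 -0.70, SLC30A1 -1.03, MT1M -1.07, XIAP -1.30, LUM -1.16, AQP3 -0.76 and PTPRO -1.67, with PTPRO -0.24 at 72 h. So did HSPE1 with centring (0.033), HSPA5 (1.09), PHLDA1 (0.18), WDR12 (0.25) and SLC30A1 (-0.32) with the mean over probe sets, and CFLAR without cross-hybridizing probe sets (0.29). With replicate numbers as a block 6659, 6529, 5399 and 2810 genes passed and 2, 10, 11 and 7 lists; DUSP1 in control cells lost its call (adjusted p = 0.0503). At 72 h equal numbers had r = -0.05, 0.14 and 0.19, and replicate 1 alone did not match its own number best, so pairing was less clear than at 24 h. Genes near the filter level have little signal over background.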

Other observations

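Gene families by the stem of their symbols were grouped after the data were seen; the tests of unnamed probe sets, opposite probe sets and short-lived transcripts were written before their results, those by signal level after the first values.

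Among 72 families of at least 15 tested genes, MRPL and RPL genes of mitochondrial and cytosolic ribosomes lay on opposite sides of the median of all genes at 24 h. Of all 10729 tested genes 2236 rose and 4343 fell, so RPL genes stood out by few falls more than by rises. Of 49 MRPL genes, which encode mitochondrial ribosomal proteins, 35 fell and 3 rose, with a median of -1.01 relative to all genes (limma's camera, adjusted p = 0.00502; adjusted p = 0.64 with an estimated correlation). Of 39 RPL genes of the cytosolic ribosome 10 rose and 3 fell, at 0.41 (adjusted p = 0.0140; adjusted p = 0.88 with an estimated correlation), but their own median was -1.67 with the spike-in scaling. IL genes, interleukins and their receptors among others, were higher at 0.89 (12 of 24 rose; adjusted p = 0.0140, or 0.64 with an estimated correlation), with an own median of -1.20 under that scaling. At 72 h 12 of 22 NUP genes of the nuclear pore rose and 2 fell, at 0.82 (adjusted p = 0.0341; adjusted p = 0.99 with an estimated correlation), with an own median of -0.18 under that scaling. In control cells over time 11 of 20 SEC genes, many of protein secretion, rose and 0 fell (0.52; adjusted p = 1.2e-04), and 8 of 22 NUP genes fell and 0 rose (-0.48; adjusted p = 2.6e-04), each with an adjusted p = 0.51 with an estimated correlation.

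Whether a lower level of short-lived transcripts at 24 h shaped these families was tested. Zinc finger genes, whose transcripts are known as short-lived, had a median of -0.054 relative to all genes (limma's camera, adjusted p = 0.95). Of 336 such genes 71 rose and 142 fell, against 2236 and 4343 of all 10729 genes. The prediction was that zinc finger genes fall and ribosomal protein genes (RPL and RPS) rise, both past the threshold. RPL genes went that way, as given above, and RPS genes are not reported here. Zinc finger genes did not pass, so the prediction was not met and the values give this explanation no support.

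Ota may have raised transcripts read by probe sets without a gene symbol. Whether these transcripts lie outside annotated genes was not determined. Among called probe sets at 24 h 64.9% of those without a symbol rose, against 37.5% of named ones, a difference of 27.4 percentage points, and 28.8 within bins of equal signal level. The difference was 16.3 at 72 h (18.7 within bins) and -6.59 in control cells over time; unnamed probe sets rose more often in 8 of the 10 bins at 24 h but in only 6 at 72 h. Ota may also have changed transcript forms within genes. Of 2775 genes with at least 2 called probe sets at 24 h, 612 (22.1%) had calls in both directions, against 12.8% at 72 h and 1.85% in control cells over time. Among probe sets with a mean over 6 the shares were 17.7%, 8.37% and 1.63%, so the mean signal level does not account for all of them. Such a mean does not keep out probe sets near background in a single group, so a part played by signal level stays open. Probe sets that read other transcripts than their annotation says were not excluded. All these shares are from the values as deposited, and with the spike-in scaling rises made up only 1.49% of the gene calls at 24 h. A rise of unnamed probe sets is therefore uncertain except relative to named ones, with median log2 fold changes of 0.30 and -0.18 at 24 h.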
